A study of Homo sapiens with 6 samples.

How the data were processed

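Total RNA of 2 human colorectal cancer cell populations was measured on Affymetrix U133 Plus 2.0 arrays, which carry several short probes for each transcript and report 1 signal per probe set. Per the labels, SW480 is the parental line and M5 a subpopulation of it with raised ability to metastasise to liver, isolated by selection in an animal. Each population has 3 arrays that the labels call biological replicates. The deposited values are probe set intensities on a linear scale, and GCOS 1.4, the array maker's software, is the tool named per the submitters' processing notes. Its settings, any scaling target and a genome build are not given in the sources used here. The table holds no detection calls, so which probe sets lay above background is unknown. The number of arrays limits the precision.

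The table has 54675 probe sets, of which 62 are control probe sets and were left out of the tests. Of the other 54613, 41091 have 1 gene symbol in the platform annotation of 2016, 1801 have several and 11721 have none. No gene was named from a probe set with several symbols or none. Symbols were checked by gene ID against a RefSeq table of assembly GRCh38.p14, which matched 41037 of the probe sets with 1 symbol and changed 0 of the symbols.

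The 2% trimmed means of the arrays differed by up to 4.12 times, far over the tolerance of 5% set in advance, so the arrays were quantile normalised. The tests used log2(signal + 1.7), the pseudocount being the 20th percentile of all deposited values. Fold changes on that scale understate differences between low signals. The 40% of probe sets with the lowest mean over all 6 arrays were left out. M5 was compared with SW480 by a linear model in limma 3.58.1 (lmFit and eBayes with an intensity trend, R 4.3.3), two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. A gene was represented by its brightest kept probe set with 1 symbol. The test, the samples, the gene lists, the rule for named genes and most alternatives were fixed before the data were examined.

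Genes were named by rule. The rule took up to 12 genes with the largest change in each direction past the threshold, with no overlap between the groups and a mean in the higher group above the median of all probe sets. It added up to 4 members past the threshold from each pathway list, and CDH1 and VIM in any case. Genes known only by a locus or clone identifier were skipped. Gene lists, 22 of pathways and 6 of other cell types, were tested with camera at an inter-gene correlation of 0.01, with an estimated correlation beside it, and with fry. Of the list symbols, 5 were matched through a synonym and 2 found no match. The members of 1 pathway list are not reported here.

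Before averaging, replicates were compared with each other and with the 39 spike-in control probe sets on each array. M5 replicates 2 and 3 were counted as 1 sample in means and SDs (n = 2 for M5) for the reason given in the results. The fit fixed in advance keeps all 6 arrays, and a fit with these 2 arrays averaged stands beside it. Other alternatives changed the scaling, the pseudocount (0.425 and 6.8), the filter (none and 60%), the variance model, the test, the probe set per gene, the replicate block and the arrays left out. Alternatives chosen after the data were seen left out the 2 dimmest arrays, weighted the arrays, or added blocks by array brightness or control signals.

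The scripts were tested on simulated signals for 32768 probe sets drawn from the real means and spreads, with 200 probe sets changed. The Wnt/beta-catenin list and a window of 50 neighbouring genes were also lowered 2-fold in M5. Those genes count neither as changed nor as unchanged in the shares and calls given next. In the simulation of all 6 arrays, 53% of the 8-fold changes and 3% of the 2-fold changes were recovered, and 1 unchanged probe set was called. In the simulation of the 4 brighter arrays, 16% of the 8-fold changes and 0% of the 2-fold changes were recovered, with 1 unchanged probe set called. The real fit of those arrays called 2572 probe sets. The simulation drew every array independently with 1 spread per probe set, so its shares do not give the power of that fit. Figures were drawn with matplotlib 3.10.9.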

Results

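Gene expression was compared between SW480, a human colorectal cancer cell line, and M5, a subpopulation isolated from SW480 by selection in an animal for metastasis to the liver. The comparison asks which transcripts differ between the parental cells and the selected cells. Each population was measured on 3 arrays. The 2% trimmed mean signals of SW480 replicates 1, 2 and 3 were 21.12, 53.78 and 87.09, and those of M5 replicates 1, 2 and 3 were 27.24, 65.89 and 67.72. SW480 replicate 1 and M5 replicate 1 were therefore the dimmest arrays, and they are called the dimmer pair here. M5 replicates 2 and 3 correlated at r = 0.994 across 3846 bright probe sets, against 0.898 to 0.958 for all other pairs of arrays. Over all kept probe sets r was 0.943 for this pair and 0.944 for SW480 replicates 2 and 3, so the pair stood apart on bright probe sets only. The median absolute deviation (MAD) of their log2 differences was 0.133 over probe sets matched in brightness to 39 spike-in controls, with a 95% range of 0.087 to 0.197 over 1000 draws. The controls themselves had a MAD of 0.09 between these arrays, inside that range. That value lay near the lower end, so the check did not separate the 2 arrays from their controls. It did not show that they differed no more than the controls either. M5 replicates 2 and 3 were counted as 1 sample in each mean and SD below. That check is weak where controls vary more: the control MAD lay inside the matched range for 5 of the 14 other pairs, 3 of them pairs of SW480 with M5. The counting therefore rests also on the MAD over bright probe sets, which was 0.113 for M5 replicates 2 and 3 and 0.299 to 0.503 for the other pairs. On bright probe sets, SW480 replicate 1 and M5 replicate 1 were closer to each other (r = 0.955, MAD 0.299) than to the rest of their own groups. There SW480 replicate 1 had r of 0.911 and MAD of 0.449 and 0.457 with SW480 replicates 2 and 3, and M5 replicate 1 had r of 0.935 and 0.933 and MAD of 0.412 and 0.417 with M5 replicates 2 and 3. Over all kept probe sets this did not hold: r was 0.895 between the dimmer arrays, 0.89 and 0.899 between SW480 replicate 1 and SW480 replicates 2 and 3, and 0.895 and 0.893 between M5 replicate 1 and M5 replicates 2 and 3. The signal of an 18S ribosomal RNA control split the arrays another way: it was 2823.9, 4163.4 and 3581.8 on SW480 replicates 1 and 2 and M5 replicate 1, and 96.3, 208.6 and 234.1 on SW480 replicate 3 and M5 replicates 2 and 3. P-values in the fit over 6 arrays still treat the replicates as the labels give them, and measure only the spread between these arrays.

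TM4SF1, which encodes a tetraspanin-like membrane protein, was higher in M5, and EHF, an epithelial transcription factor of the ETS family, and PKIB, an inhibitor of protein kinase A, were lower. TM4SF1 signal was 20.4 ± 20.8 (SD, n = 3) in SW480 and 499 ± 38 (SD, n = 2) in M5, a log2 fold change of 4.94 with a standard error (SE) of 0.55 and an adjusted p of 0.0126 in limma. All 3 of its probe sets passed the threshold. EHF signal was 947 ± 387 (SD, n = 3) in SW480 and 29.5 ± 15.2 (SD, n = 2) in M5, a log2 fold change of -4.75 (SE 0.38, limma adjusted p = 0.00123). All 6 EHF probe sets pointed the same way and 4 passed. PKIB signal was 1470 ± 270 (SD, n = 3) in SW480 and 181 ± 91.8 (SD, n = 2) in M5, a log2 fold change of -2.91 (SE 0.29, limma adjusted p = 0.00465). With M5 replicates 2 and 3 averaged, these genes stayed past the threshold in limma, with adjusted p of 0.045 for TM4SF1, 0.00256 for EHF and 0.0098 for PKIB. That fit also called SPARC, a matrix glycoprotein gene, lower in M5 (log2 fold change -3.49, SE 0.46, limma adjusted p = 0.0466), which in the 6-array fit had an adjusted p of 0.0725 (SE 0.60). Its signals were 9.07, 1.43 and 16.7 on M5 replicates 1, 2 and 3, so the arrays averaged in that fit differed for this gene, and averaging them lowered the SE. SPARC was named after its values were seen.

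In the fit over all 6 arrays, 8 of 14243 genes were higher in M5 and 6 were lower. The higher genes beside TM4SF1 were MYL2, VHRT, TCN1, ANXA3 and the metallothionein genes MT1H, MT1F and MT1X, which encode metal-binding proteins. MYL2, a muscle myosin light chain gene, had a signal of 3.45 ± 3.38 (SD, n = 3) in SW480, near the bottom of the scale, and 81.1 ± 17.9 (SD, n = 2) in M5. TCN1, which encodes a vitamin B12-binding protein, had a log2 fold change of 2.78 (SE 0.41, limma adjusted p = 0.0471), and VHRT one of 2.88 (SE 0.33, limma adjusted p = 0.0126). ANXA3, an annexin gene, had a log2 fold change of 1.33 (SE 0.19, limma adjusted p = 0.0412). The log2 fold changes of MT1H, MT1F and MT1X were 1.92, 1.22 and 0.96, with limma adjusted p of 0.0144, 0.0321 and 0.0471. Their probe sets are marked by the array maker as shared between similar sequences, so which metallothionein rose is uncertain.

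The lower genes beside EHF and PKIB were SOX4, PAPSS2, MAN1A1 and SMIM3. SOX4, a transcription factor gene, fell from 2370 ± 1300 (SD, n = 3) to 418 ± 57.3 (SD, n = 2), a log2 fold change of -2.41 (SE 0.30, limma adjusted p = 0.0157). PAPSS2, which encodes an enzyme that makes the sulfate donor of the cell, had a log2 fold change of -1.82 (SE 0.22, limma adjusted p = 0.0144). MAN1A1, a mannosidase gene of glycoprotein processing, had one of -1.81 (SE 0.23, limma adjusted p = 0.0163), and SMIM3 one of -1.45 (SE 0.22, limma adjusted p = 0.0487). Of the kept probe sets, 2 of 6 passed for SOX4, 1 of 3 for PAPSS2 and 1 of 2 for each of MAN1A1, MT1F and MT1X. Their other kept probe sets pointed the same way without passing. Each of the 14 genes had the same direction on the dimmer pair as on the other arrays, and the same direction within the arrays of high and of low 18S control signal. As the genes were named for groups that do not overlap over these arrays, their direction in any subset was fixed by the choice. The log2 differences in these sets were 4.95 and 5.06 for TM4SF1, -5.2 and -4.88 for EHF and -3.56 and -2.7 for PKIB. With the 18S control as a block, limma called 8 genes higher and 7 lower. CDH1, the gene of the epithelial adhesion protein E-cadherin, had a log2 fold change of 0.05 (SE 0.21, limma adjusted p = 0.965), and VIM, the gene of vimentin, one of -0.06 (SE 0.41, limma adjusted p = 0.975). With M5 replicates 2 and 3 averaged, only 1 gene was higher and 3 were lower, and limma adjusted p for the other 11 of the 14 genes lay between 0.061 and 0.323. Without the intensity trend in limma, 0 genes were called, against 8 higher and 6 lower with it. At an unadjusted p under 0.05, limma gave 568 genes higher and 616 lower without the trend and 773 and 871 with it.

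**Figure D1:**
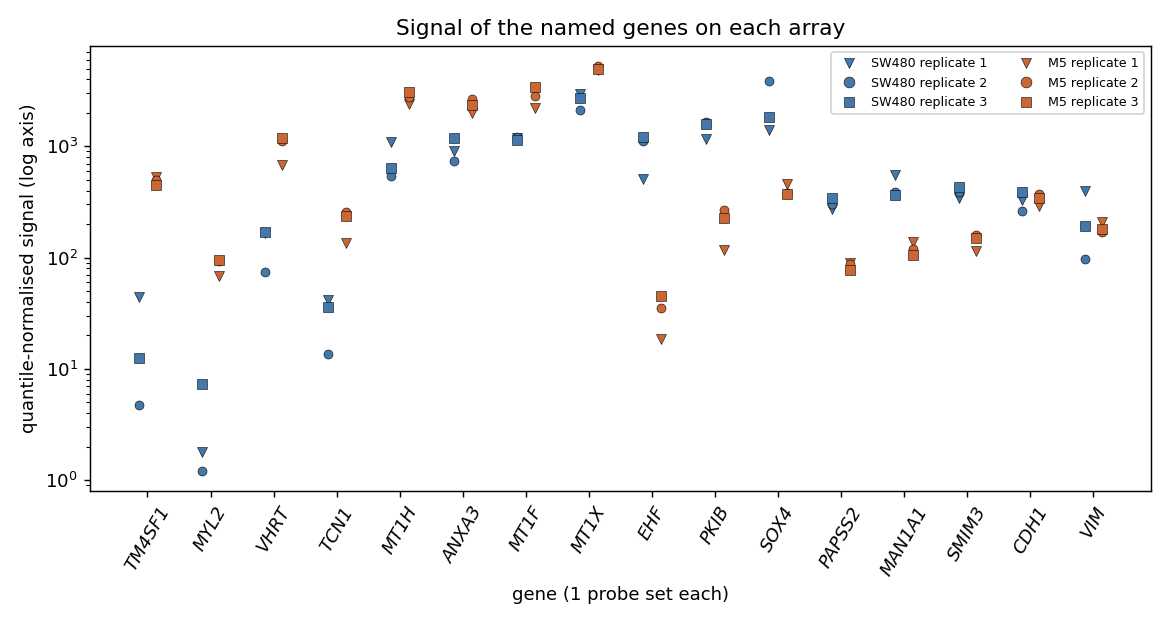
Quantile-normalised signal (log axis) of the 14 genes past the threshold and of CDH1 and VIM, with 1 point per array, blue for SW480 and orange for M5, and triangles for the dimmer pair. TM4SF1 lies between 4.7 and 43.9 on the SW480 arrays and between 452 and 526 on the M5 arrays, while CDH1 and VIM overlap between the groups.

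Among 22 pathway lists, cell cycle and proliferation genes stood higher in M5 as a set, with a median log2 fold change of 0.15 over 53 measured members and a camera adjusted p of 0.0481 in limma. The set's adjusted p was 0.962 with an estimated correlation and 0.051 with M5 replicates 2 and 3 averaged, and limma's fry gave an unadjusted p of 0.165. None of the 53 passed singly, and the median was 0.11 within the arrays of high and 0.15 within those of low 18S control signal. Wnt/beta-catenin targets had a median of -0.32 over 30 members and a camera adjusted p of 0.0562 in limma, or 0.962 with an estimated correlation. SOX4 was lower among them over all genes tested. Adjusted over the list alone, 2 Wnt targets were lower, SOX4 and the growth factor gene BMP4, and 1 was higher, TROAP. The other 20 pathway lists had camera adjusted p between 0.23 and 0.922 in limma.

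Single members of further lists passed when adjusted over the list alone, but not over all genes. In the epithelial list, the transcription factor gene ELF3 (log2 fold change 1.46, SE 0.26) and the desmosomal cadherin gene DSC2 (1.09, SE 0.24) were higher. ITGA2, an integrin subunit gene that binds collagen, was lower in the adhesion list (-1.96, SE 0.40). In the mesenchymal list, SPARC (-3.58, SE 0.60) and COL3A1 (-1.31, SE 0.33) were lower and the receptor kinase gene AXL (1.41, SE 0.33) higher. In the interferon list, OAS1 (-1.67) and IFI44 (-1.38) were lower and SAMD9 (1.11) higher. The receptor kinase list gave AXL and IGFBP6 (2.18) higher and IER3 (-0.82) lower. IGFBP6 signals were 306, 57.3 and 55.4 on SW480 arrays and 283, 533 and 629 on M5 arrays, in replicate order. The groups thus overlapped for this gene. In the TGF-beta list, CCN2 (2.07) was higher and BMP4 (-2.61) lower, the stress list gave ATF3 (1.47) higher and the cytokine list TNFRSF21 (-1.41) lower. Limma adjusted p over all genes for these members lay at 0.0678 or above. On the dimmer pair, IGFBP6 and SAMD9 differed by -0.11 and 0.07. The other members given as higher, ELF3, DSC2, AXL, CCN2 and ATF3, differed there by 0.71, 0.75, 0.84, 1.35 and 0.94. Among those given as lower, SPARC, TNFRSF21, BMP4 and ITGA2 differed there by -3.2, -0.98, -0.7 and -0.59. Dimmer-pair values of COL3A1, OAS1, IFI44 and IER3 are not given here. BMP4 signals were 116, 93.1 and 96.8 on SW480 arrays and 70.8, 5.08 and 8.15 on M5 arrays, in replicate order.

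None of the 6 lists of other cell types (fibroblast, endothelial, leukocyte, erythroid, hepatocyte, adipocyte and muscle) passed, with camera adjusted p between 0.645 and 0.977 in limma. In that order, the members measured were 10 of 14, 4 of 10, 9 of 14, 3 of 8, 10 of 16 and 5 of 10. With so few members, these tests cannot show that RNA of such cells was absent. Adjusted over the list alone, COL3A1 was lower among fibroblast markers and TTR higher among hepatocyte markers. TTR, the gene of the liver protein transthyretin, had signals of 196, 73.1 and 5.68 on M5 replicates 1, 2 and 3 and at most 5.17 on the SW480 arrays.

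Without the dimmer pair, an alternative chosen after the data were seen, limma called 615 genes higher and 766 lower among 14162. With M5 replicates 2 and 3 also averaged, leaving 2 SW480 samples against 1 M5 sample, 97 were higher and 142 lower. The spread then came from SW480 replicates 2 and 3 alone, which differ in the 18S control, and the lone M5 sample was assumed to vary like them. Of the 2572 probe sets called on the 4 brighter arrays, 53.3% had the same sign on the left-out dimmer pair. The share was 58.3% for those higher in M5, 48.9% for those lower, and 61.9% for the 97 that differed at least 8-fold. The median dim-pair difference was 0.03 of that on the brighter arrays, 0.1 for those higher and -0.02 for those lower. All 24 probe sets called over 6 arrays had the same sign there, for which they were in part chosen.

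**Figure D2:**
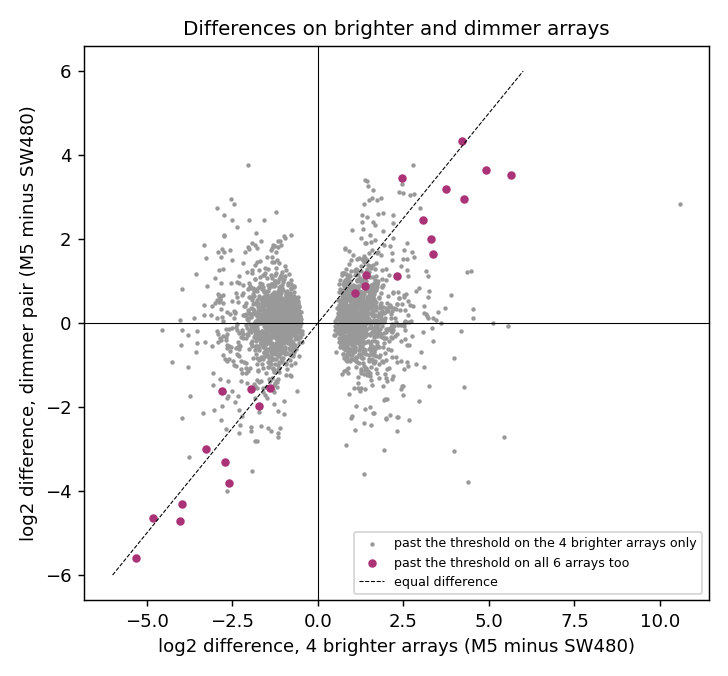
Log2 difference between M5 and SW480 on the 4 brighter arrays (horizontal axis) and on the dimmer pair (vertical axis) for the 2572 probe sets past the threshold on the brighter arrays, with the 24 also past it over all 6 arrays in purple and a dashed line of equal difference. Most grey points scatter around 0 on the vertical axis.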

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

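The alternatives that left out the dimmer pair, weighted the arrays, averaged M5 replicates 2 and 3, or used the dim-array block or the control-probe block were chosen after the data were seen. The fit over 6 arrays gave 13 probe sets higher and 11 lower in M5, 8 genes higher and 6 lower, 1 pathway list higher and 0 lower, and 0 lists of other cell types. Across the 22 alternatives, none of the 14 genes changed sign. They were named for groups that do not overlap, so leaving out, averaging or weighting arrays could hardly change their sign. EHF stayed past the threshold in 20 alternatives, PKIB in 19, TM4SF1 in 17 and MT1X in 7.

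Scaling and filter: with no scaling between arrays, 6 probe sets and 3 genes were lower, 0 pathway lists and 2 lists of other cell types were higher; with arrays centred on the median, 3 pathway lists were higher. These scalings moved the median of all probe sets to 0.06 and 0.07 on the log2 scale. The smaller pseudocount gave 5 genes higher, the larger pseudocount and the stricter filter each 0 pathway lists higher, and no filter 20 probe sets and 11 genes lower. Test: limma without trend gave 0 probe sets and 0 genes higher, 1 probe set and 0 genes lower; the plain t-test, Benjamini-Hochberg adjusted, gave 0 in each direction. An estimated correlation gave 0 pathway lists higher. The cause of these shifts was not tested.

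Arrays: without the dimmer pair, 1194 probe sets and 615 genes were higher and 1378 and 766 lower, with 4 pathway lists higher and 1 lower; with M5 replicates 2 and 3 averaged as well, these were 172 and 97, 297 and 142, 3 and 1. With an estimated correlation no pathway list passed in either fit (adjusted p of at least 0.759 and 0.942). Without the dimmer pair, the 4 lists higher did not include cell cycle and proliferation, the list called over 6 arrays (camera adjusted p = 0.263). Array weights gave 845 and 446 higher, 1069 and 591 lower, with 2 pathway lists higher and 1 lower. The dim-array block gave 48 and 31 higher, 32 and 17 lower, and 1 pathway list lower. M5 replicates 2 and 3 averaged gave 2 and 1 higher, 7 and 3 lower, and 0 pathway lists higher. The interferon list, with a camera adjusted p of 0.558 and direction down over 6 arrays, was up without the dimmer pair (0.0399) and with M5 replicates 2 and 3 averaged as well (0.0256), calls lost with an estimated correlation (adjusted p of 0.759 and 0.942).

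Leaving out 1 array in turn gave 1 to 165 probe sets and 0 to 86 genes higher, 3 to 212 probe sets and 2 to 111 genes lower, 0 to 2 pathway lists higher, 0 to 2 lower, and 0 to 1 lists of other cell types higher. Genes higher and lower were 79 and 36 without SW480 replicate 1, 86 and 111 without M5 replicate 1, 2 and 4 without SW480 replicate 2, 3 and 2 without SW480 replicate 3, 0 and 2 without M5 replicate 2, and 1 and 2 without M5 replicate 3. The replicate numbers gave no clear pairing of the samples. Deviations from the group means correlated at 0.11, 0.02 and 0.07 for equal numbers 1, 2 and 3. The value for number 1 was the highest of all combinations, while SW480 replicate 3 correlated best with M5 replicate 2 (0.08). The replicate block gave 18 probe sets lower and 1 pathway list lower. Without detection calls, signals near the bottom of the scale, such as MYL2 in SW480, set no firm fold.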

Other observations

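All tests of explanations in this part were chosen after the results were seen. On the 4 brighter arrays, further genes are given with limma's log2 fold change for M5 replicates 2 and 3 averaged and with their difference on the dimmer pair. They are a part of the genes that the naming rule gives on these arrays, picked after the values were seen. No p is given, as the spread would come from SW480 replicates 2 and 3 alone. EMP1, an epithelial membrane protein gene, had a log2 fold change of 3.76 and a dim-pair difference of 0.35. TM4SF18, a relative of TM4SF1, had 4.43 and 1.21. The chemokine receptor gene CXCR4 had -3.97 and -1.74, and the Wnt target AXIN2 -1.78 and -0.59. CXCR4 signals were 5.52, 39 and 44.6 on SW480 arrays and 0.467, 3.28 and 0.383 on M5 arrays, in replicate order. The M5 signals lay around the pseudocount of 1.7, so they set no firm fold. The laminin gene LAMB3 had 2.48 and -0.43, and the protease genes KLK10 and KLK6 had 2.2 and 1.54 against -0.36 and -0.48. The fatty acid receptor gene CD36 had -4.14 and 0.81. Its signals were 1.8, 24.1 and 166 on SW480 arrays and at most 5.02 on M5 arrays.

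With 10 splits of the 6 arrays into 3 and 3, no share under 0.05 can be reached. The real split gave 24 probe sets and 14 genes, as many as no other split (1 of 10 each), and the highest of the others gave 2 and 1. It gave 1 pathway list, where all 10 splits gave at least as many and the highest other 7, and 0 lists of other cell types, a count that every split reaches (highest other 1), so that comparison tests nothing. At an unadjusted p under 0.05 in limma the real split gave 3360 probe sets. The split that follows the 18S control (SW480 replicates 1 and 2 with M5 replicate 1) gave 3364, of which 0 stayed after adjustment, and SW480 replicate 1 with M5 replicates 2 and 3 gave 3075, so the arrays hold structure beside the groups. With the 18S control as a block, 11 probe sets were higher and 13 lower in M5.

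The differences on the 4 brighter arrays were mostly absent from the dimmer pair, whose arrays, SW480 replicate 1 and M5 replicate 1, lay 37% and 40% of the way from SW480 to M5. Over 802 bright probe sets called there, the median dim-pair difference was 0.04 of that on the brighter arrays (bootstrap interval 0 to 0.08), which argues against random noise in the dimmer pair, expected near 1, and against exchanged labels, expected near -1. Compression of the whole log2 scale on the dimmer arrays is argued against by the spread of deposited log2 signals across these probe sets. It was 1.01 of that on the brighter arrays (0.98 to 1.04), the last of several measures tried for this explanation. That spread is taken across genes, so it cannot tell whether the difference between the lines alone was compressed, which stays open. Of 555 bright genes called there, 32 went the same way on the dimmer pair by over 3 MAD and 13 the opposite way, a share of 0.71 (exact interval 0.56 to 0.84; Fisher's exact p = 0.0076, two-sided, between the direction on the brighter arrays and on the dimmer pair), which argues against a single wrong label, expected near 0.5, though genes are not independent and a 4-fold limit tried first left too few (4 and 1). A state of the cultures, a processing batch shared by the dimmer pair, or M5 replicates 2 and 3 being 1 sample may account for it; the labels give no batch, the 18S control splits the arrays another way, and the difference between the lines stays open too.

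Several digestive enzyme genes of the pancreas stood high on M5 replicates 2 and 3 only: PRSS2 had signals of 1830 and 1590 there, 63 on M5 replicate 1 and at most 66.4 on SW480 arrays, and CELA3B 158 and 172 against at most 23.6 elsewhere. Human pancreas RNA mixed into these samples would bring other abundant acinar transcripts too. For 16 of these the median log2 difference was 0.6 (bootstrap interval 0.08 to 0.98), against 3.18 for the 7 genes seen. PNLIP had signals of 4.93 and 2.7 on M5 replicates 2 and 3. The differences of PNLIPRP1, CPA1 and REG3A were larger, at 2.23, 1.85 and 1.43, with mean signals of 18.6, 8 and 14 there. As the 7 genes were picked for being high, a lower median in the rest was in part fixed by that choice. The comparison therefore cannot decide whether such RNA was mixed in. Cross-hybridization between paralogs alone stays open: 2 genes, CELA1 and CPB1, differed at least 4-fold on probe sets not marked as shared, but they were picked for the pattern and their signals were low. As both arrays count as 1 sample, a difference of that culture stays open. On the dimmer pair the 7 genes differed by -2.71 (CELA3B) to 1.24 (CTRB2), and PRSS2 by -0.07. M5 replicate 1 thus did not share the rise of PRSS2 and CELA3B. It is 1 array of the dimmer pair, where most differences were absent, so a difference of the line stays open too.

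A stretch of chromosome 7 held 225 neighbouring genes, from ZNF117 to SRPK2 (gene order of GRCh38.p14), with CD36 and SAMD9 among them. For each gene, deviations were taken from its median over all 6 arrays, SW480 replicate 1 included. Over the stretch, the median log2 deviation of SW480 replicate 1 was -0.63 (bootstrap interval -0.82 to -0.51), against 0.02 to 0.1 for each other array. Of the 556 windows of 50 genes, 8 on chromosome 7 passed 1000 shuffles of the gene order on SW480 replicate 1. That array also passed, upward, from MICB to HLA-DOA on chromosome 6 (0.4) and from IGFBP2 to SGPP2 on chromosome 2 (0.39). On SW480 replicate 3, 10 windows passed with deviations of at most 0.41. Among them were NT5DC1 to STX7 on chromosome 6 (0.39) and BET1L to SYT8 on chromosome 11 (-0.38). Another, GNAI1 to SEM1, lay within the chromosome 7 stretch and was higher (0.3). The low brightness of the dimmer arrays is argued against by M5 replicate 1, at 0.06 (-0.02 to 0.17). A lower copy number in the culture of SW480 replicate 1 is a candidate explanation. The stretch, found again on 150 less bright genes alone, held 22 brighter genes. Of these, 22 were lower on SW480 replicate 1, with a median of -0.82 (-1.01 to -0.64). M5 replicates 2 and 3 shifted the other way over these genes, with medians of 0.21 (0.09 to 0.49) and 0.19 (0.05 to 0.47). On those arrays 3 and 5 of the 22 genes were lower. DNA was not measured, and another stock of cells was not tested. On the 4 brighter arrays, 11 of 551 overlapping windows shifted together between the lines beyond the shuffles, and in 8 of them the median went the opposite way on the dimmer pair. Whether copy number differs between the lines there is open, since 1 of the 11 also shifted the same way on the dimmer pair, from DSE to RPS12 on chromosome 6 (median log2 difference -0.48 and -0.22, one-sided permutation p = 0.0221 against 10000 random gene sets, not adjusted for the 11 windows), where M5 replicates 2 and 3 differed by -0.41 from SW480 replicate 2 and by -0.5 from SW480 replicate 3; of the 11 windows, 8 differed more from SW480 replicate 3 and 3 more from SW480 replicate 2.

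A probe set with no gene symbol in the annotation used, picked for its large difference, had deposited signals of 10.5, 18 and 1.1 on SW480, 80.4 on M5 replicate 1, and 14807 and 14629.2 on M5 replicates 2 and 3, where it ranked 22 and 24 among all probe sets. Among hepatocyte markers, FGB had signals of 202, 23.8 and 9.33 on M5 replicates 1, 2 and 3 and FGG 238, 19.1 and 13.3, against at most 11.2 on SW480 arrays.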
